A study of Homo sapiens with 18 samples.

How the data were processed

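Polyadenylated RNA was sequenced from PANC-1 cells treated with 0.5 µM or 5 µM PRLX-93936 or with DMSO vehicle for 2 h or 6 h, with 3 libraries in each of 6 groups and 18 in all. Groups, doses, times and replicate numbers were taken from the sample titles. According to the series text, the authors quantified gene expression with nf-core/rnaseq 3.12.0 and Salmon 1.10.1 on hg38, and the annotation behind their gene names is not stated. The values used in the tests are the deposited gene-level estimated counts, which the authors made by summing Salmon's estimates over the transcripts of a gene. A second deposited table holds estimated counts rebuilt from TPM with a gene length shared by the libraries, and another holds deposited TPM (abundance relative to all transcripts of a library), summed per gene, and these served as alternatives. A further deposited table, which rescales TPM to library totals without gene length, holds nothing that the TPM table lacks and was not used. The transcript tables were not used either, because their transcripts carry running numbers that the files do not pair with transcript names. The count table had 0 per-sample columns left unused.

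Estimated counts were rounded, genes were kept by edgeR's filterByExpr with the 6 groups, and libraries were scaled by TMM. Of 29744 genes, 13890 were tested. Library totals ran from 12295057 to 21424141, and the biological coefficient of variation was 9.16%. The median 95% half-width of a log2 fold change was 0.257, 0.258, 0.262 and 0.262 for 0.5 µM and 5 µM at 2 h and 0.5 µM and 5 µM at 6 h, each against vehicle. Spread and intervals cover the variation between these libraries only, and they say nothing of other cultures or cell lines.

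The test throughout was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3; glmQLFit with robust spread, glmQLFTest) on all 18 libraries with 1 mean per group, which left 12 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The comparisons were each dose with vehicle at each time, 5 µM with 0.5 µM at each time, the difference of each dose's effect between 6 h and 2 h (an interaction), and vehicle at 6 h with vehicle at 2 h. Every fold change is treated over vehicle, 5 µM over 0.5 µM, or later over earlier, so that positive values are rises.

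Before the data were examined, 39 gene lists were fixed, of which 35 had the 5 tested members that a list test needed. They were tested with camera at a preset correlation of 0.01 between genes, with the correlation estimated from the data, and with fry, and adjusted over lists and over the 4 comparisons with vehicle. In the other 5 comparisons they were adjusted over lists and those 5. Fry tests whether the genes of a list move, on balance, in 1 direction, and does not compare them with other genes. The rule for named genes was fixed at the same time. For each comparison with vehicle it takes the 8 largest rises and the 8 largest falls among called genes with at least 5 CPM in the higher group, a symbol that is not a clone, LOC or antisense name, and treated and vehicle libraries that do not overlap in log2 CPM. It adds up to 4 members with the smallest p in each list, and TRIM21, NUP98, MYC and MCL1 whether called or not. For the comparison of the doses and the interactions it takes the 5 largest rises and falls, and for the interactions the libraries must not overlap at either time. A gene named in 1 comparison was allowed in others. COL1A2, LYZ, FN1, SPP1, LOX, MAL2, CDH13 and other genes of the library sets were named after their values were seen.

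Exon number, gene length and position came from GENCODE release 29 (GRCh38), matched by current or former symbol for 13297 of the tested genes (95.7%). Of these, 12702 were protein-coding genes with an exon number, that of the APPRIS principal transcript or else the longest, 284 with 1 exon and 12418 with more. Fisher's exact test compared calls between these classes, and differences in GC, length and expression were matched in 1-point GC bins or with the 20 nearest multi-exon genes, with 2000 bootstrap draws. Correlations of effects between comparisons were set against 20 simulated experiments without effects, since both doses share vehicle libraries. Shares of counts were compared by exact two-sided permutation tests, whose smallest p is 0.1 with 3 libraries against 3.

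Alternatives planned before the data were examined were DESeq2's size factors, library totals and the housekeeping list in place of TMM, no filter beyond 1 count, a filter at 5 CPM in at least 3 libraries, DESeq2 1.42.0, limma 3.58.1 on log2 TPM with pseudocounts of 1 and 0.1, the length-scaled counts, fits of only the libraries of the groups compared, replicate numbers from titles or library names as blocks, an adjusted p under 0.01, a change of at least 2-fold, and each library of the groups compared left out in turn. Added after the data were seen were scaling to the mitochondrial rRNAs, a correction of each library for GC content (lowess span 0.3), terms for libraries holding COL1A2 or LYZ above 1 CPM, and leaving out vehicle replicate 2 at 6 h from the comparisons that do not use it. The closing section gives their effects.

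The pipeline was tested on simulated data in which known changes were planted at 5 µM and 2 h. For the recovery of single genes, a GC trend was also planted in vehicle replicate 2 at 6 h, which favours the GC correction. The main test recovered 40.3%, 76.1% and 95.5% of genes planted at 1.5-fold, 2-fold and 4-fold (67, 67 and 66 genes) and called 2 unchanged genes. DESeq2 recovered 53.7%, 85.1% and 97.0% and called 6, limma recovered 40.3%, 76.1% and 97.0% and called 1, and the GC correction recovered 59.7%, 86.6% and 97.0% and called 5. Camera called the 1 list that was raised and 0 of the unchanged lists. A planted single-exon shift of -0.5 was recovered as -0.49 with GC bins and as -0.43 without matching.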

Results

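The series measured polyadenylated RNA in PANC-1, an established human pancreatic carcinoma cell line, after exposure to the compound PRLX-93936 or to its vehicle, dimethyl sulfoxide (DMSO). PRLX-93936 is known here by its code name, and it has been reported to recruit the ubiquitin ligase TRIM21 to proteins of the nuclear pore. There were 6 groups of 3 libraries each, 18 in all: vehicle, 0.5 µM and 5 µM, each after 2 h and after 6 h. The labels do not say whether replicates were separate cultures beyond triplicate wells, so p-values measure the spread between these samples. The library names number the 18 libraries from 1 to 23 and their replicates from 1 to 5, so some numbers are absent. Whether libraries were left out is not stated. Total estimated counts per library ran from 12295057 to 21424141. Of 29744 genes in the table, 13890 had enough counts to test, and they held 99.9% of all counts. The biological coefficient of variation between replicates was 9.16%, and the median 95% half-width of a log2 fold change was 0.26 in the 5 µM comparison at 2 h. Values are TMM-scaled CPM, counts scaled to a common library size, with SD (CPM without TMM factors for the library sets at the end), and log2 fold changes with SE, with n = 3 in every group. The lists of genes, the tests and the rule for which genes are named were chosen before the data were examined, while the grouping of genes by exon number and the library sets described at the end were chosen after.

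The comparison of 0.5 µM with vehicle at 2 h asks which transcripts had moved early at the lower dose. Targets of NF-κB, a transcription factor of inflammatory signalling, were among the largest rises of genes that met the rule for naming, which asks for at least 5 CPM in the higher group and libraries that do not overlap. NFKBIA, which encodes the NF-κB inhibitor IκBα (chromosome 14, 35401511 to 35404749, GRCh38), rose 15.5-fold, from 32.7 ± 1.95 to 510.1 ± 13.1 CPM (log2 3.96 ± 0.09). TNFAIP3, a ubiquitin-editing brake on NF-κB, rose 12.9-fold, from 8.01 ± 0.396 to 103 ± 5.58 CPM. The chemokine gene CXCL3 rose 30.5-fold from a low level, 0.172 ± 0.0483 to 5.72 ± 1.46 CPM. The largest fall by that rule was that of IER5L, an intronless gene on chromosome 9 (129175552 to 129178262), which dropped from 37.9 ± 3.78 to 6.70 ± 0.823 CPM (log2 -2.50 ± 0.21). MCL1, an anti-apoptotic gene with a short-lived transcript (chromosome 1, 150574551 to 150579738), fell from 209 ± 6.75 to 106 ± 4.43 CPM (log2 -0.98 ± 0.09).

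Of the 25 NF-κB targets tested, 21 rose and 0 fell (23 and 0 adjusted over the list alone), with a median log2 change of 1.64 (camera adjusted p = 3.7e-156, and adjusted p = 9.7e-08 with an estimated correlation). They included CXCL1 (3.46 ± 0.16), a chemokine that draws neutrophils, BIRC3 (1.71 ± 0.13), an inhibitor of apoptosis, and ICAM1 (1.64 ± 0.07), an adhesion molecule. Other large rises were those of IRF1, an interferon-linked transcription factor (3.58 ± 0.10), the stress kinase NUAK2 (3.14 ± 0.17), the ephrin ligand EFNA1 (3.12 ± 0.11) and the activation marker CD69 (3.04 ± 0.31). Among 26 immediate-early genes, 14 rose and 2 fell (14 and 4 adjusted over the list alone), such as KLF6 (1.44 ± 0.10) and ATF3 (1.51 ± 0.15), both stress-induced transcription factors, and PPP1R15A (0.91 ± 0.09), which restores translation after stress. That list had a median of 0.64 (adjusted p = 7.2e-15, but adjusted p = 0.0795 with an estimated correlation). Of 22 targets of the growth regulator YAP, 5 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 1.28e-05, and adjusted p = 0.0205 with an estimated correlation). The matricellular protein gene CYR61 went from 321 to 703 CPM (1.13 ± 0.06).

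Of 423 genes of zinc finger proteins, 77 fell at 0.5 µM and 2 h and 1 rose (112 and 4 adjusted over the list alone), with a median of -0.26 (adjusted p = 4.09e-11, but adjusted p = 0.074 with an estimated correlation). ZNF830 (-1.69 ± 0.14), ZNF503 (-1.62 ± 0.20) and ZNF581 (-0.99 ± 0.11) were among them. Large falls were also seen for SOX21, a developmental transcription factor (-2.07 ± 0.21), MARS2, the mitochondrial methionyl-tRNA synthetase (-1.80 ± 0.15), PPP1R3D, a glycogen-targeting phosphatase subunit (-1.66 ± 0.20), and ZCCHC3, a nucleic acid-binding cofactor of innate immune sensors (-1.59 ± 0.14). HEXIM1 (-0.84 ± 0.09) and MEPCE (-0.82 ± 0.10), which restrain the elongation factor P-TEFb, fell together with ID1, an inhibitor of differentiation factors (-1.22 ± 0.11). The forkhead gene FOXD2 fell (-1.62 ± 0.38), a call lost with the smaller TPM pseudocount, with the library-name replicate block and without replicate 1 of the 0.5 µM group at 2 h. The list of 30 short-lived regulators went both ways, with 6 up and 10 down (8 and 11 adjusted over the list alone). Its median was -0.16, its mean was 0.08 and camera called it up (adjusted p = 0.0132, but adjusted p = 0.281 with an estimated correlation). Splicing factors, nuclear transport, interferon and proteasome genes were called up by camera as lists, with 4, 3, 3 and 1 members up and 1, 0, 4 and 0 down, and adjusted p = 0.143, 0.33, 0.199 and 0.524 with an estimated correlation. Adjusted over the list alone, those lists had 4, 3, 8 and 1 members up and 1, 0, 5 and 0 down, and the interferon list had a median of -0.00 but a mean of 0.34. TRIM21 had a log2 value of -0.01 ± 0.09, NUP98, a nuclear pore gene, 0.13 ± 0.06 and MYC 0.14 ± 0.08, and none of the 3 passed the test.

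In all, 247 genes rose and 719 fell at 0.5 µM and 2 h by edgeR's quasi-likelihood test, with 78 up and 98 down by at least 2-fold. The count of rises was 156, 152 and 163 without vehicle replicates 1, 2 and 3 at 2 h, 156 without replicate 1 of the 0.5 µM group at 2 h, and 588 without vehicle replicate 2 at 6 h, which shares the estimate of spread. Falls numbered 432 without that 0.5 µM library and 1118 without that vehicle library. With the library sets as terms there were 78 rises and 168 falls, and with the GC correction 843 and 1177. Rises made up 25.6% of the calls, 15.6% with libraries scaled to housekeeping genes and 46.8% with scaling to the mitochondrial rRNAs.

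**Figure D1:**
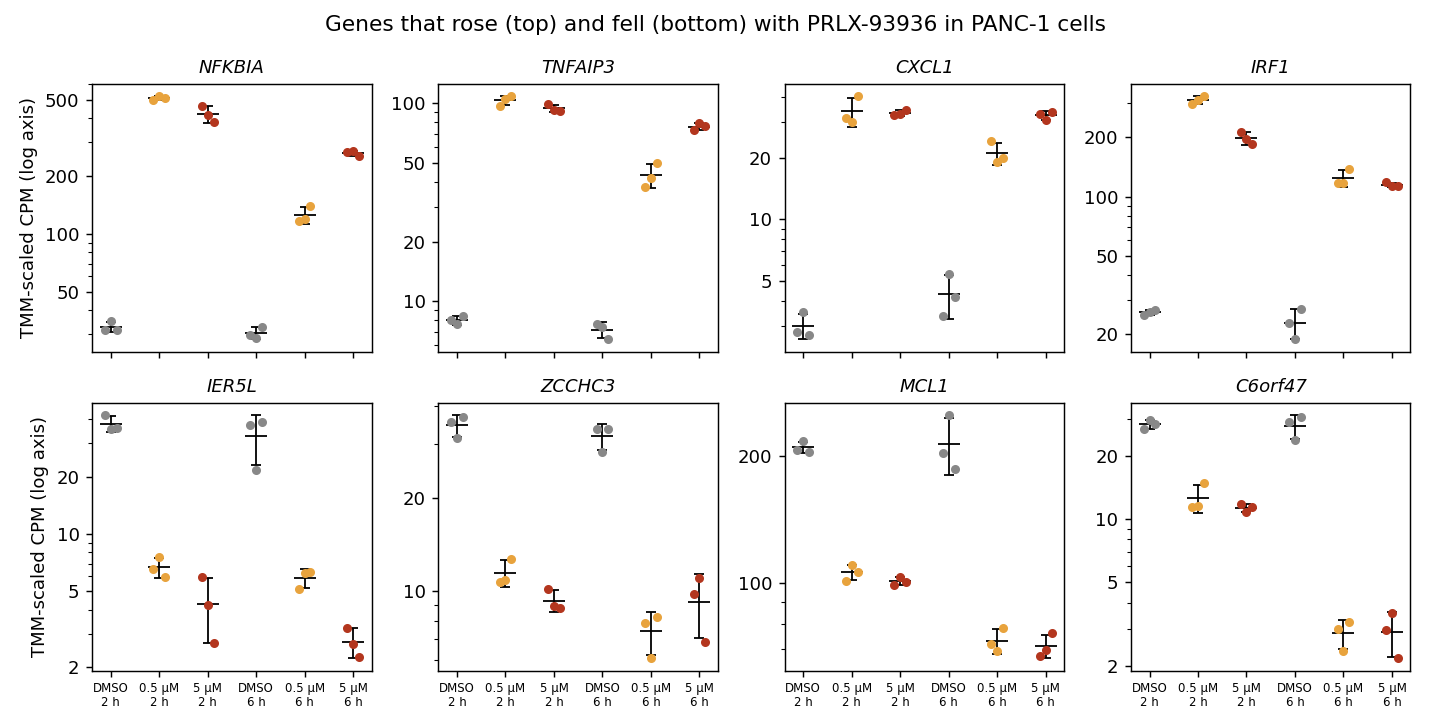
TMM-scaled CPM (log axis) of 8 genes in the 6 groups, with 1 point per library and bars for mean and SD, n = 3 per group. NFKBIA was at 32.7 CPM in the vehicle libraries at 2 h and at 510.1 CPM in the 0.5 µM libraries.

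At 5 µM and 2 h, the question was which early changes came with the higher dose. Among genes that met the rule for naming, NF-κB targets again held the largest rises. CXCL2 rose 28.8-fold, from 0.263 ± 0.188 to 7.26 ± 1.11 CPM, and NFKBIA rose 12.8-fold to 419.9 CPM (log2 3.68 ± 0.09). NFKBIZ, a nuclear regulator of NF-κB, rose from 6.94 to 54.9 CPM (2.97 ± 0.12). IER5L fell 8.88-fold to 4.28 ± 1.62 CPM (log2 -3.15 ± 0.22), and MCL1 fell from 209 to 101 CPM (-1.05 ± 0.09).

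Of the 25 NF-κB targets, 20 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 1.12 (adjusted p = 6.66e-92, and adjusted p = 9.68e-07 with an estimated correlation). CXCL3 (4.96 ± 0.40), TNFAIP3 (3.56 ± 0.10), CXCL1 (3.43 ± 0.16) and BIRC3 (1.69 ± 0.13) were among them. IRF1 (2.93 ± 0.10) and NUAK2 (2.85 ± 0.17) rose beside them. Among the immediate-early genes 11 rose and 5 fell (12 and 5 adjusted over the list alone), with KLF6 at 1.36 ± 0.10, ATF3 at 1.42 ± 0.16, and IER5, a stress-response gene without introns, at -1.76 ± 0.17. Their median was 0.45 (adjusted p = 0.000235, but adjusted p = 0.396 with an estimated correlation). YAP targets numbered 5 up and 1 down (6 and 3 adjusted over the list alone; adjusted p = 0.000614, but adjusted p = 0.0506 with an estimated correlation), with CYR61 at 1.02 ± 0.06. Of 30 splicing genes, 10 rose and 1 fell (11 and 2 adjusted over the list alone; adjusted p = 0.00863, but adjusted p = 0.0983 with an estimated correlation). TRA2A, a splicing activator, was at 0.35 ± 0.06 and the splicing kinase CLK4 at 0.90 ± 0.11. Among 30 nuclear transport genes, 12 rose and 1 fell (16 and 1 adjusted over the list alone), such as the importin KPNA4 (0.42 ± 0.08). The list median was 0.19 (adjusted p = 0.000184, but adjusted p = 0.217 with an estimated correlation). The nuclear RNA MALAT1 (1.15 ± 0.18) and the polymerase I cofactor gene TAF1D (1.03 ± 0.13) also rose.

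The zinc finger genes held 141 falls and 4 rises at 5 µM and 2 h (182 and 10 adjusted over the list alone), with a median of -0.38 (adjusted p = 1.44e-14, and adjusted p = 0.049 with an estimated correlation). ZNF830 (-1.86 ± 0.14) and ZNF581 (-1.25 ± 0.11) fell. So did MARS2 (-2.16 ± 0.16), the forkhead genes FOXQ1 (-2.10 ± 0.22) and FOXC2 (-2.07 ± 0.26), C15orf39 (-2.03 ± 0.20) and ZCCHC3 (-1.89 ± 0.14). The list of TGF-β targets had 3 members up and 8 down (3 and 10 adjusted over the list alone), among them ID1 (-1.68 ± 0.11), ID3 (-1.08 ± 0.12) and the mesenchymal regulator SNAI1 (-1.67 ± 0.16). Its median was -0.22 (adjusted p = 0.00339, but adjusted p = 0.313 with an estimated correlation). The short-lived regulators held 6 rises and 12 falls (6 and 14 adjusted over the list alone) and were not called as a list (adjusted p = 0.348). Other falls were those of CHAC1, a glutathione-degrading stress gene (-1.41 ± 0.19), the pro-apoptotic BCL2L11 (-0.92 ± 0.11), MEPCE (-0.96 ± 0.10), the ubiquitin-conjugating mitotic gene UBE2C (-0.59 ± 0.09) and the chaperone DNAJB1 (-0.53 ± 0.06). Of 32 nuclear pore genes, 5 rose and 3 fell (6 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.0978). TRIM21 fell slightly (-0.33 ± 0.10, adjusted p = 0.026), with adjusted p between 0.06 and 0.13 under 8 alternatives. NUP98 rose slightly (0.21 ± 0.06, adjusted p = 0.022), a call that was also lost under several. MYC was at -0.17 ± 0.08 and did not pass the test.

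There were 806 rises and 1264 falls at 5 µM and 2 h, with 70 up and 200 down by at least 2-fold. Rises numbered 355, 398 and 280 without vehicle replicates 1, 2 and 3 at 2 h, 313 and 247 without 5 µM replicates 2 and 3, and 1919 without vehicle replicate 2 at 6 h. Falls numbered 810 without vehicle replicate 3 at 2 h, 806 and 788 without those 5 µM libraries, and 2109 without that vehicle library. With the library-name replicate block there were 165 rises and 657 falls, and with the GC correction 1385 and 1548. Rises were 38.9% of the calls, 14.9% with housekeeping scaling and 1.10% with mitochondrial rRNA scaling, which put the median of all genes at -0.48. The latter scaling rests on 2 genes. They held 0.31 ± 0.05% of counts at 5 µM and 0.24 ± 0.06% in vehicle at 2 h (exact two-sided permutation test, p = 0.3).

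By 6 h at 0.5 µM, the comparison asks how the lower dose had altered the transcriptome later on. MYLK2, a myosin light chain kinase best known from skeletal muscle (chromosome 20, 31819308 to 31834689), rose 13.8-fold, from 0.562 ± 0.161 to 7.93 ± 0.734 CPM (log2 3.78 ± 0.25). ARRDC3, an arrestin-domain protein gene, went from 46.3 ± 8.99 to 356 ± 31.5 CPM (2.94 ± 0.12), and CYR61 from 329 ± 21.5 to 1912 ± 74.7 CPM (2.54 ± 0.06). C6orf47, a single-exon gene on chromosome 6 (31658298 to 31660772), fell 9.65-fold, from 27.7 ± 3.59 to 2.86 ± 0.453 CPM. MCL1 fell from 213 ± 33.2 to 73.0 ± 4.86 CPM (-1.54 ± 0.09).

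Of the 25 NF-κB targets, 21 rose and 2 fell at 0.5 µM and 6 h (22 and 2 adjusted over the list alone), with a median of 1.33 (adjusted p = 5.95e-25, and adjusted p = 0.000331 with an estimated correlation). TNFAIP3 (2.59 ± 0.10), NFKBIZ (2.46 ± 0.12), NFKBIA (2.04 ± 0.09) and ICAM1 (2.00 ± 0.07) rose, as did the activation marker CD83 (2.67 ± 0.09), the transcriptional repressor PRDM1 (2.94 ± 0.16) and IRF1 (2.44 ± 0.10). The falls in the list were those of BIRC2 (-0.51 ± 0.12) and IER3 (-0.45 ± 0.10), 2 genes that protect from apoptosis. Immediate-early genes held 17 rises and 6 falls (18 and 7 adjusted over the list alone), with a median of 0.60 (adjusted p = 5.96e-05, but adjusted p = 0.376 with an estimated correlation). In that list FOS (3.44 ± 0.59) and FOSB (2.91 ± 0.71) rested on replicate 3 of the 0.5 µM group, at 22.9 and 22.3 CPM: without it their log2 values were 2.21 and 1.35, and FOSB also lost its call with the library sets as terms. Of the YAP targets, 9 rose and 6 fell (10 and 6 adjusted over the list alone; adjusted p = 5.96e-05, and adjusted p = 0.0309 with an estimated correlation). CTGF was at 1.58 ± 0.07 and LATS2, a kinase that restrains YAP, at 1.42 ± 0.09. Cholesterol synthesis genes held 8 rises and 0 falls (8 and 0 adjusted over the list alone; adjusted p = 0.00524, but adjusted p = 0.0795 with an estimated correlation). The sterol synthesis enzyme gene HMGCS1 was at 1.30 ± 0.11. MYC rose (0.82 ± 0.08, or 0.53 with housekeeping scaling). The readthrough transcript FAM24B-CUZD1 was at 2.69 ± 0.71, with reads that its parent genes can share.

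Genes of RNA processing and of the cell's basic machinery also rose at 0.5 µM and 6 h. Of 23 mRNA export genes, 13 rose and 3 fell (14 and 3 adjusted over the list alone; adjusted p = 0.000467, but adjusted p = 0.0506 with an estimated correlation). They included the export helicases DDX39A (1.49 ± 0.10) and DDX39B (1.21 ± 0.06) and the export receptor NXF1 (0.90 ± 0.07). Splicing genes held 19 rises and 4 falls (19 and 5 adjusted over the list alone; adjusted p = 0.00112, but adjusted p = 0.0506 with an estimated correlation), such as TRA2B (0.71 ± 0.05). Ribosomal protein genes rose in 69 of 70 cases with 0 falls (70 and 0 adjusted over the list alone), with a median of 0.45 (adjusted p = 1.81e-15, but adjusted p = 0.396 with an estimated correlation). Of 31 proteasome genes, 26 rose and 1 fell (26 and 1 adjusted over the list alone), with a median of 0.33 (adjusted p = 6.27e-06, but adjusted p = 0.199 with an estimated correlation). Respiratory chain genes held 28 rises and 1 fall of 36 (31 and 1 adjusted over the list alone), with a median of 0.31 (adjusted p = 0.000115, but adjusted p = 0.417 with an estimated correlation). In these last lists PSMD11, a lid subunit of the proteasome (-0.19 ± 0.06), and UQCRFS1, an iron-sulfur subunit of complex III (-0.48 ± 0.06), were the falls. RPL6 (0.47 ± 0.05) and PSMA6 (0.47 ± 0.06) were among the rises. With housekeeping scaling the medians of the ribosomal protein, proteasome and respiratory chain lists were 0.16, 0.03 and 0.02, and with TPM 0.19, 0.06 and 0.04, so the rise of the last 2 lists depended on the scaling. A further 6 lists were called up by camera with the preset correlation and not with an estimated one, and fry called them too. Host genes of small nucleolar RNAs had 11 members up and 2 down (adjusted p = 0.461 with an estimated correlation), nuclear transport genes 12 and 2 (adjusted p = 0.417) and integrated stress response genes 16 and 5 (adjusted p = 0.313). Unfolded protein response genes had 10 up and 2 down (adjusted p = 0.114 with an estimated correlation), TGF-β targets 10 and 6 (adjusted p = 0.417) and housekeeping genes 15 and 0 (adjusted p = 0.288). Adjusted over the list alone, these lists had 11, 12, 17, 10, 10 and 15 members up and 2, 2, 5, 2, 6 and 0 down. The short-lived regulators held 16 rises and 9 falls (16 and 9 adjusted over the list alone; adjusted p = 0.00116, but adjusted p = 0.165 with an estimated correlation). The kinase genes PIM1 (1.71 ± 0.08) and PLK2 (1.20 ± 0.06) were among the rises. With housekeeping scaling the median of the short-lived regulators was 0.01 in place of 0.31. That of all genes was -0.29 in place of 0.01. The shift over all genes exceeded the medians of the mRNA export (0.28), splicing (0.21) and nuclear transport (0.15) lists. It also exceeded those of the unfolded protein response (0.14), TGF-β (0.27) and cholesterol (0.12) lists, so these rises depended on the scaling too.

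Falls at 0.5 µM and 6 h took in 228 of 423 zinc finger genes, against 33 rises (237 and 35 adjusted over the list alone), with a median of -0.52 (adjusted p = 3.56e-07, but adjusted p = 0.164 with an estimated correlation). SOX21 (-3.56 ± 0.25), SPIN4, a chromatin reader gene (-3.22 ± 0.22), TSPYL5 (-3.19 ± 0.14), ZNF488 (-3.18 ± 0.16), the protease gene ADAMTS15 (-3.12 ± 0.09), the tRNA-modifying TRMT12 (-3.05 ± 0.23) and the ubiquitin ligase adaptor KLHL9 (-3.05 ± 0.16) were among the largest falls of genes that met the rule for naming. HEXIM1 (-1.87 ± 0.09) and MEPCE (-1.67 ± 0.10), the tight junction gene CLDN4 (-1.85 ± 0.11), the mitotic phosphatase CDC25B (-1.60 ± 0.10), CDKN1A, the p21 cell cycle inhibitor (-1.11 ± 0.12), and CDK1 (-1.01 ± 0.10) fell too. TRIM21 rose (0.53 ± 0.10, adjusted p = 0.00014, or 0.24 with housekeeping scaling and 0.28 with TPM). NUP98 was at 0.14 ± 0.06 and did not pass the test. Of 32 nuclear pore genes, 6 rose and 7 fell (6 and 7 adjusted over the list alone), with NUP62 at -0.73 ± 0.08. Their median was 0.04 and their mean -0.01, and the list was not called (adjusted p = 0.807).

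The test called 3097 rises and 3358 falls at 0.5 µM and 6 h, 321 and 1075 of them by at least 2-fold. Rises were 48.0% of the calls, 11.0% with housekeeping scaling, which put the median of all genes at -0.29, 27.5% with library totals, which put it at -0.13, and 17.8% with TPM, which put it at -0.17. The zinc finger falls and the NF-κB and ribosomal protein rises kept their direction under every scaling run, the ribosomal proteins at a median of 0.16 with housekeeping scaling. Single-exon genes were followed only as a difference from multi-exon genes, which a scaling that moves all genes together cannot test.

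After 6 h at 5 µM, NF-κB targets stood highest among genes that met the rule for naming. CXCL2 rose 53.2-fold, from 0.153 ± 0.155 to 8.60 ± 0.906 CPM, NFKBIA 8.66-fold to 263 ± 8.04 CPM (log2 3.11 ± 0.09) and TNFAIP3 10.6-fold to 76.3 ± 2.99 CPM (3.41 ± 0.10). IER5L fell 12.1-fold, from 32.5 ± 9.51 to 2.71 ± 0.486 CPM. CDK1, the kinase that drives entry into mitosis, fell 4.87-fold, from 161 ± 31.0 to 32.9 ± 1.72 CPM (-2.29 ± 0.11), and MCL1 fell 3.00-fold to 70.9 ± 4.62 CPM.

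The NF-κB list held 21 rises and 1 fall at 5 µM and 6 h (22 and 1 adjusted over the list alone), with a median of 1.62 (adjusted p = 1.91e-28, and adjusted p = 0.00021 with an estimated correlation). CXCL3 (5.20 ± 0.42), ZC3H12A, a ribonuclease of inflammatory mRNAs (2.93 ± 0.12), NFKBIZ (2.85 ± 0.12) and ICAM1 (1.62 ± 0.07) were among them, and IER3 fell (-0.72 ± 0.10). FERMT3, the integrin activator kindlin-3 (3.36 ± 0.24), MYLK2 (3.35 ± 0.25), ARRDC3 (3.01 ± 0.12) and NUAK2 (2.90 ± 0.18) also rose. Immediate-early genes went both ways, with 12 up and 8 down (13 and 8 adjusted over the list alone; adjusted p = 0.0341, but adjusted p = 0.613 with an estimated correlation). YAP targets did so too, with 8 up and 6 down (8 and 6 adjusted over the list alone). Their median was -0.04 and their mean 0.23, and camera called them up (adjusted p = 0.0177, but adjusted p = 0.164 with an estimated correlation). Splicing genes held 19 rises and 4 falls (19 and 6 adjusted over the list alone; adjusted p = 0.000171, and adjusted p = 0.0309 with an estimated correlation). The splicing kinases CLK4 (1.38 ± 0.11) and CLK1 (1.24 ± 0.09) were among them. All 70 ribosomal protein genes rose (70 adjusted over the list alone), with a median of 0.48 (adjusted p = 8.33e-17, but adjusted p = 0.385 with an estimated correlation). Proteasome genes rose in 24 of 31 cases and fell in 1 (25 and 2 adjusted over the list alone; adjusted p = 9.17e-05, but adjusted p = 0.278 with an estimated correlation). Their median of 0.30 was -0.00 with housekeeping scaling and -0.01 with mitochondrial rRNA scaling. Respiratory chain genes held 30 rises and 1 fall (31 and 1 adjusted over the list alone; adjusted p = 2.96e-05, but adjusted p = 0.396 with an estimated correlation). Their median of 0.33 was 0.03 with housekeeping scaling, 0.02 with mitochondrial rRNA scaling and 0.05 with TPM. Nuclear transport, small nucleolar RNA host and housekeeping genes were again called up by camera with the preset correlation and not with an estimated one, and fry called them too. They had 11, 12 and 16 members up and 2, 2 and 0 down, with the same counts adjusted over the list alone (adjusted p = 0.471, 0.396 and 0.278 with an estimated correlation). Housekeeping scaling put the median of all genes at -0.30 in place of 0.01. That shift exceeded the medians of the nuclear transport (0.12) and splicing (0.24) lists, so their rises depended on the scaling too.

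Cell division genes fell at 5 µM and 6 h: of 30 G2/M genes, 22 fell and 0 rose (23 and 0 adjusted over the list alone), with a median of -0.38 (adjusted p = 8.01e-07, but adjusted p = 0.199 with an estimated correlation). Beside CDK1, these were genes such as UBE2C (-1.47 ± 0.09), CDC25B (-1.32 ± 0.10) and the mitotic kinase AURKA (-0.96 ± 0.07). Among zinc finger genes 271 fell and 23 rose (280 and 26 adjusted over the list alone), with a median of -0.74 (adjusted p = 4.14e-12, but adjusted p = 0.0579 with an estimated correlation). FAM156A, which has a near-identical copy that can share its reads, fell by 3.70 ± 0.77 on the log2 scale. CCDC71 (-3.44 ± 0.26), ZBTB3 (-3.28 ± 0.27), C6orf47 (-3.26 ± 0.16), CCDC8 (-3.15 ± 0.21), TSPYL5 (-3.06 ± 0.14) and SOX21 (-3.02 ± 0.24) fell too. The integrated stress response list had 12 members up and 7 down (12 and 8 adjusted over the list alone) and was not called (adjusted p = 0.648). CHAC1 (-2.16 ± 0.21), the mTOR inhibitor DDIT4 (-1.95 ± 0.10) and HMOX1, which degrades haem (-1.53 ± 0.11), fell. The chaperone genes DNAJB1 (-1.49 ± 0.06) and HSPA8 (-1.02 ± 0.08) fell too, in a heat shock list with 10 members up and 7 down. BCL2L11 (-1.79 ± 0.12), SOX4 (-1.93 ± 0.08), E2F2 (-1.76 ± 0.14), PMEPA1, a feedback inhibitor of TGF-β signalling (-1.70 ± 0.07), and SPRY2, a feedback inhibitor of growth factor signalling (-1.52 ± 0.14), fell. Nuclear pore genes held 5 rises and 10 falls of 32 (5 and 10 adjusted over the list alone; adjusted p = 0.659), among them NUP62 (-0.79 ± 0.08) and NUP153 (-0.63 ± 0.07). TRIM21 fell (-0.46, adjusted p = 0.00074), while NUP98 (-0.01) and MYC (0.06) did not pass the test.

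Counts at 5 µM and 6 h were 3201 up and 3549 down, 276 and 1126 of them by at least 2-fold. Rises were 47.4% of the calls, 10.0% with housekeeping scaling, which put the median of all genes at -0.30, 27.7% with library totals (-0.13), 15.7% with TPM (-0.18) and 5.82% with mitochondrial rRNA scaling (-0.30).

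**Figure D2:**
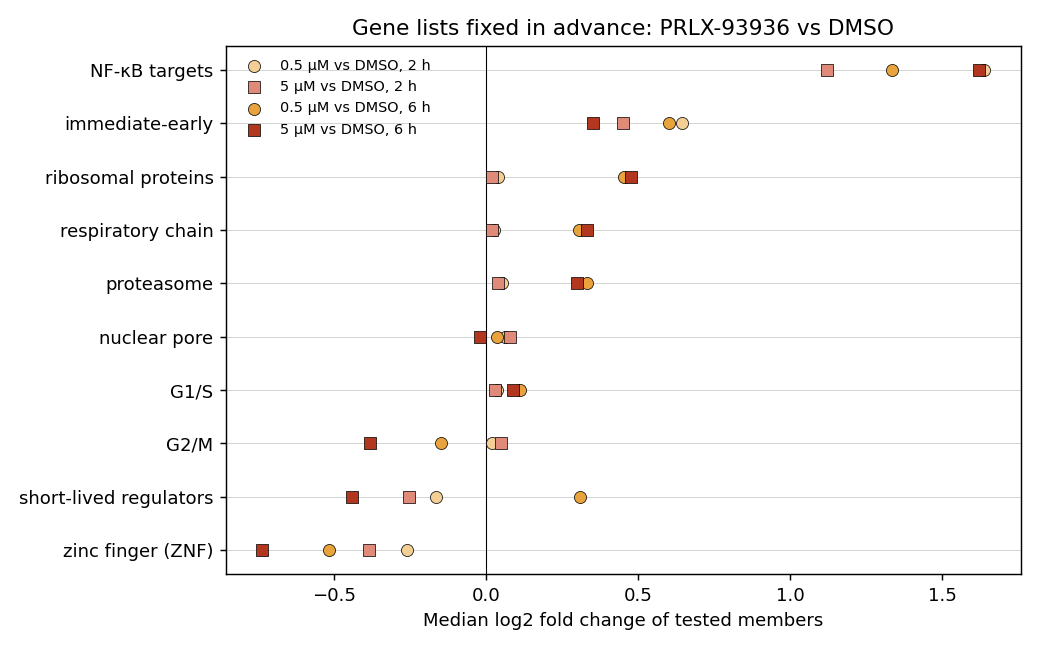
Median log2 fold change of the tested members of 10 gene lists in the 4 comparisons with vehicle, n = 3 libraries per group. NF-κB targets had medians of 1.64, 1.12, 1.33 and 1.62, and zinc finger genes -0.26, -0.38, -0.52 and -0.74.

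Genes with few exons fell more often than others in every comparison with vehicle. Of 284 single-exon protein-coding genes tested, 110 fell at 0.5 µM and 133 at 5 µM after 2 h, and 188 and 163 fell after 6 h, while 3, 2, 10 and 15 rose. These were 38.7%, 46.8%, 66.2% and 57.4% of single-exon genes, against 4.66%, 8.67%, 23.5% and 25.7% of 12418 multi-exon genes. The odds ratio at 0.5 µM and 2 h was 12.9 (95% interval 9.94 to 16.8; Fisher's exact test, two-sided, p = 2.879e-66, with genes as the units although genes are not independent replicates). At that dose and time the median log2 change was -0.49 in single-exon genes, -0.32 in genes with 2 exons, -0.10 with 3 or 4 exons, -0.01 with 5 to 8 and 0.05 with 17 or more. At 0.5 µM and 6 h the single-exon median reached -1.20. IER5L, IER5, ZCCHC3 and C6orf47 belong to this class, and MCL1 has 3 exons. Without the histone and zinc finger genes, 108, 131, 182 and 159 of 258 single-exon genes fell. Between the doses at 6 h the order was the other way, with 60 single-exon genes higher at 5 µM and 4 lower (median 0.28).

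**Figure D3:**
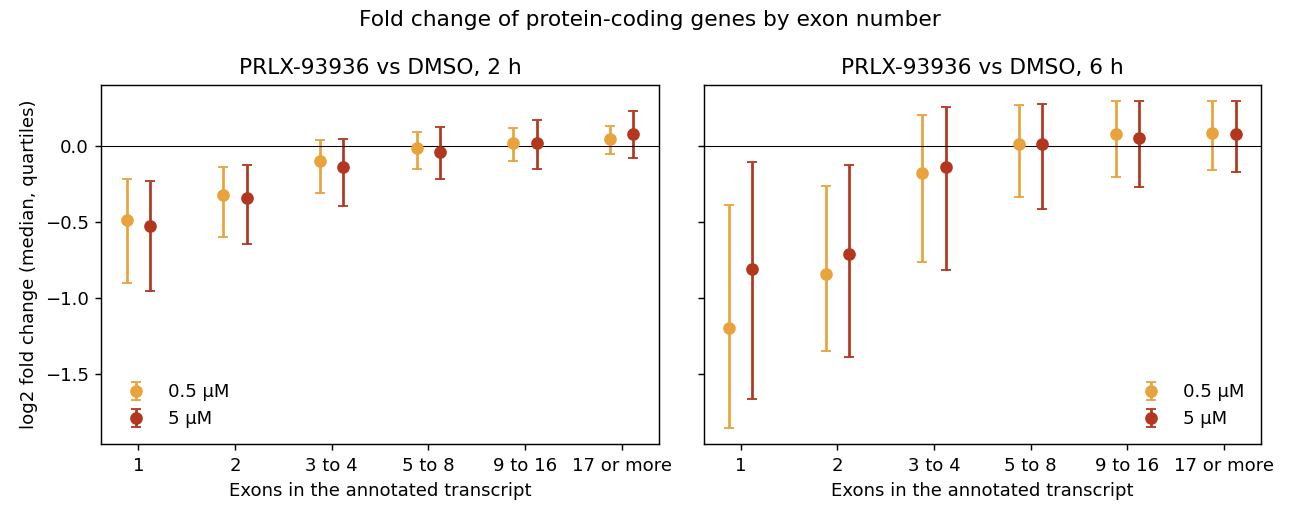
Median log2 fold change against vehicle (vertical axis) of protein-coding genes by annotated exon number (horizontal axis), at 2 h and 6 h, for 0.5 µM and 5 µM, with bars for the quartiles. At 0.5 µM and 6 h the medians ran from -1.20 in 284 single-exon genes to 0.09 in 2711 genes with 17 or more exons.

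The direct comparison of 5 µM with 0.5 µM asks where the doses differed. At 2 h NFKBIZ was higher at 5 µM (0.76 ± 0.11), as was the cyclin gene CCNL1 (0.58 ± 0.09), and EFNA1 (-0.68) and IRF1 (-0.65) were lower, as were CHAC1 (-1.02 ± 0.20), BCL3 (-0.83) and PDGFB (-0.60). These were among 2 rises and 16 falls, and all 7 of these genes lost their calls with the library-name replicate block and with the library sets as terms. The counts were 0 and 3 without 0.5 µM replicate 1, 1 and 5 without 0.5 µM replicate 2, and 26 and 98 without vehicle replicate 2 at 6 h. Falls numbered 6 without 0.5 µM replicate 3 and 3 and 4 without 5 µM replicates 2 and 3. With mitochondrial rRNA scaling the counts were 29 and 5136, and the median of all genes was -0.52.

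After 6 h, NFKBIA (1.07 ± 0.08), CXCL3 (1.36 ± 0.28), the phosphatase gene DUSP8 (1.10), HEXIM1 (1.07 ± 0.09) and the transporter gene SLC45A3 (1.02) were higher at 5 µM than at 0.5 µM, CXCL3 losing its call with the smaller TPM pseudocount. TBX15, a developmental transcription factor (-1.38), DDIT4 (-1.31 ± 0.10), SPRY1 (-1.31), the retinoic acid receptor RARA (-1.31) and ID1 (-1.30 ± 0.11) were lower. Of the short-lived regulators, 19 were lower and 2 higher (19 and 3 adjusted over the list alone; adjusted p = 2.27e-17, and adjusted p = 0.00769 with an estimated correlation). TGF-β targets had 12 lower and 0 higher (13 and 1 adjusted over the list alone; adjusted p = 2.96e-15, and adjusted p = 0.0256 with an estimated correlation). Cholesterol synthesis genes had 10 lower and 0 higher (12 and 1 adjusted over the list alone; adjusted p = 1.3e-07, and adjusted p = 0.00809 with an estimated correlation). Among G2/M genes 12 were lower and 0 higher (15 and 1 adjusted over the list alone; adjusted p = 1.64e-09, but adjusted p = 0.15 with an estimated correlation). In all 547 genes were higher and 1104 lower at 5 µM. The count of rises was 316, 299 and 360 without 0.5 µM replicates 1, 2 and 3, 327, 346 and 320 without 5 µM replicates 1, 2 and 3, and 954 without vehicle replicate 2 at 6 h. Rises were 33.1% of the calls and 0.799% with mitochondrial rRNA scaling, which put the median of all genes at -0.36.

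The doses shared 171 rises and 629 falls at 2 h, against 14.3 and 65.4 for independent lists, and 2419 and 2670 at 6 h, against 714 and 858, with 0 and 58 genes called in opposite directions. Both doses used the same vehicle libraries, which alone makes effects correlate across genes: Pearson r was 0.542 at 2 h and 0.816 at 6 h, against 0.500 ± 0.0352 (SD over 20 simulations) and 0.483 in simulated groups without any effect. The covariance was 0.115 against 0.0479 simulated at 2 h and 0.436 against 0.0484 at 6 h, and simulated groups shared 0 calls. Between 2 h and 6 h, which share no libraries, r was 0.540 at 0.5 µM and 0.428 at 5 µM, and 217 and 497 rises and 649 and 1101 falls were shared. These correlations are across genes, which are not independent replicates.

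The difference of the effects between 6 h and 2 h was tested as an interaction. Among genes that met the rule for naming, MYLK2 gained most by 6 h at 0.5 µM (interaction log2 4.11), with the neurotrophin receptor gene NGFR (2.09) and the metabolic regulator TXNIP (1.90), and CD69 (-2.67), SPIN4 (-2.65) and TSPYL5 (-2.60) lost most. At 5 µM MYLK2 (3.54), FERMT3 (2.41) and NGFR (2.17) gained, and FAM156A (-4.21), CCDC71 (-2.50) and ZBTB3 (-2.44) lost. At 0.5 µM 1091 genes had a higher effect at 6 h and 1572 had a lower effect. The first count was 1728 without vehicle replicate 3 at 6 h, 652 without 0.5 µM replicate 3 at 2 h and 708 without 0.5 µM replicate 2 at 6 h. Both counts depended on scaling: they were 247 and 3373 with housekeeping scaling, 309 and 2704 with TPM, and 44 and 177 with mitochondrial rRNA scaling. At 5 µM the counts were 1623 and 2080. The first was 966 without 5 µM replicate 3 at 2 h and 996 without 5 µM replicate 1 at 6 h. With the same scalings the 5 µM counts were 356 and 4486, 454 and 3467, and 47 and 72.

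Between the vehicle groups at 6 h and 2 h, edgeR's quasi-likelihood test called 0 genes, with 690 at an unadjusted p under 0.05 and 0 genes by DESeq2 and by limma. It called 1 rise without vehicle replicate 3 at 6 h. Camera called 8 of 35 lists between these groups, 2 up and 6 down, and 0 with an estimated correlation. Ribosomal protein genes had 0 members up or down and a median of -0.11 (adjusted p = 2.26e-10, but adjusted p = 0.465 with an estimated correlation), which was -0.02 without vehicle replicate 2 at 6 h. Ribosomal protein genes held 5.00 ± 0.64% of counts in vehicle libraries at 6 h and 6.29 ± 0.15% and 6.37 ± 0.16% at 0.5 µM and 5 µM (exact two-sided permutation test, p = 0.1 each, the smallest that 3 against 3 allows).

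Libraries also differed in sets of genes that followed the treatment only in part. COL1A2, a collagen of mesenchymal cells, stood at 8.26 ± 1.39 CPM (SD, 7 libraries) in all vehicle libraries at 2 h, vehicle replicates 2 and 3 at 6 h, replicate 1 of 0.5 µM at 6 h and replicate 3 of 5 µM at 2 h, and near 0 in the rest. LYZ, which encodes lysozyme, stood at 3.87 ± 0.467 CPM (6 libraries) in all libraries of 0.5 µM at 2 h, replicates 2 and 3 of 0.5 µM at 6 h and replicate 1 of 5 µM at 6 h. These libraries held FN1, the fibronectin gene, at 2.24 ± 0.727 CPM against 27.6 ± 14.7 and 24.2 ± 10.4 CPM in the others. At 2 h these sets coincide with vehicle and 0.5 µM, so for their genes the set and the treatment cannot be told apart there. Every library with LYZ was a treated one, and most libraries with COL1A2 were vehicle ones, so the sets were uneven over treatment at 6 h too. Of 35 tested genes of these sets, 11 were called up and 4 down at 0.5 µM and 2 h, 0 and 0 at 5 µM and 2 h, 15 and 4 at 0.5 µM and 6 h, and 8 and 2 at 5 µM and 6 h. LYZ was called up at 0.5 µM after 2 h and 6 h and at 5 µM after 6 h (6.95 ± 1.62, 5.84 and 4.92). The lists of mesenchymal, leukocyte, NRF2 and interferon genes hold members of these sets, among them IFI27, an interferon-stimulated gene with a log2 value of 3.89 ± 1.05 at 0.5 µM and 2 h, where camera called that list up. The mesenchymal genes had 0 up and 1 down, 1 and 1, 6 and 1, and 8 and 2 in the 4 comparisons with vehicle. The 4 leukocyte genes measured, too few for a list test, had 1, 0, 3 and 3 up and 0 down.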

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

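Chosen only after the results were seen were the tests of genomic DNA and of the zinc finger class, all tests of the library sets, and the splits that exchange times in the interactions.

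The effect of each dose differed between 6 h and 2 h by a test of the difference itself, the interaction of edgeR's fit. At 0.5 µM 1091 genes had a higher and 1572 a lower effect at 6 h, and at 5 µM 1623 and 2080. Among genes that met the rule for naming, the largest gains at 0.5 µM were in MYLK2 (log2 4.11), NGFR (2.09), TXNIP (1.90), SOCS3 (1.81) and NR1D1 (1.74), and the largest losses in CD69 (-2.67), SPIN4 (-2.65), TSPYL5 (-2.60), HOMEZ (-2.44) and ZNF488 (-2.29). At 5 µM, by the same rule, the largest gains were in MYLK2 (3.54), FERMT3 (2.41), NGFR (2.17), MYH3 (1.85) and NR1D1 (1.79), and the largest losses in FAM156A (-4.21), CCDC71 (-2.50), ZBTB3 (-2.44), TSPYL5 (-2.41) and SPIN4 (-2.40).

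Among 100 splits that exchanged times within the treated and within the vehicle libraries, 3 called as many genes as the real split or more, the real split included, at 0.5 µM (2663 genes, highest other 3412) and likewise 3 of 100 at 5 µM (3703 genes, highest other 4597). These splits do not decide whether chance can be excluded, because exchanging the times of treated libraries brings their difference between 6 h and 2 h into the spread, and the median of the other splits was 0 genes at each dose. In the highest split at both doses the treated libraries kept their times and only vehicle libraries were exchanged, and 0 genes were called between the vehicle groups (690 at an unadjusted p under 0.05, and 0 by DESeq2 and limma). An earlier version that exchanged treated and vehicle libraries within a time gave 12 of 100 splits as large at 0.5 µM (highest 5693) and 9 of 100 at 5 µM (highest 6274). Its highest split was the exchange of all treated with all vehicle libraries at 1 time, which adds the effects in place of subtracting them. With 3 libraries against 3 there are 10 splits, which cannot give a share under 0.05. The real split called 966, 2070, 6455 and 6750 genes in the 4 comparisons with vehicle and 18 between the doses at 2 h, with 0 as the highest other in each, and 1651 between the doses at 6 h, with 7 as the highest other, so that in these 6 comparisons 1 of 10 splits was as large. For vehicle at 6 h against 2 h the real split called 0 genes and the highest other 10, and 10 of 10 splits called as many.

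Protein-coding genes with 1 exon fell more often than others in every comparison with vehicle, and the tests here used 5 µM at 2 h. GC content as the whole cause was argued against by a difference of -0.43 (95% interval -0.54 to -0.35) from multi-exon genes of the same GC, and transcript length and expression level by a difference of -0.47 (-0.52 to -0.37) from the nearest multi-exon genes. Genomic DNA in the vehicle libraries was argued against by olfactory receptor genes, at 0.00193 CPM per gene against a median loss of 9.26 CPM, a ratio of 0.000209. The zinc finger class as the whole cause was argued against by a Spearman rho of 0.34 (0.26 to 0.43) between exon number and fold change within that class. An effect of the treatment on transcripts with few introns may remain as a hypothesis, found and tested on the same data. Transcript half-life and nuclear export were not measured, and a link of exon number with either was not tested.

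Vehicle replicate 2 at 6 h stood apart from its group (chi-square per gene 28.5 and 36.5 against the others and 4.74 between those), and so did vehicle replicate 1 at 2 h (19.8 and 15.4, and 2.69), whose deviation had r = 0.0181 with GC content. Cytosolic rRNA genes held 3.15% of counts in that library at 2 h, against 0.907% and 0.925% in the others of its group. Their part in its deviation was not tested, nor was another cause. A wrong label that hides a treated library was argued against by the NF-κB list of the library at 6 h, whose mean log2 CPM lay -0.18 from that of the other 5 vehicle libraries (3.13 against 3.31 ± 0.056), away from the treated libraries at 5.02. The deviation exceeds 1 SD, the bound written beforehand, but that bound did not consider a deviation in this direction. A GC bias in library preparation or sequencing is a candidate explanation, for the library at 6 h, since its deviation from the other 2 libraries of its group had r = -0.682 with GC content across genes, which are not independent replicates. This r was the largest in size, but sizeable values were not particular to that library. They reached 0.518 in vehicle replicate 3 at 6 h and 0.413 in replicate 2 of 0.5 µM at 2 h. The design gives no biological explanation within a group, so none was tested.

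COL1A2 was present in 7 libraries and LYZ in 6 others, with both near 0 in the other 5. The treatment as the only cause was argued against because 4 of the 6 groups held libraries of more than 1 of these sets. In 3 groups libraries with and without COL1A2 occurred together, and in 2 groups those with and without LYZ. The sets were still uneven over treatment, since every library with LYZ was treated and most with COL1A2 were vehicle libraries. A small admixture of RNA or reads from other cells is a candidate explanation. Between the sets, 0 of 7435 genes with a mean of at least 20 CPM were called, and the 10 genes called had means up to 8.22 CPM. This does not decide the question, because the sets partly coincide with treatment, so the fit can miss large differences. FN1, at 2.24 CPM with LYZ against 27.6 and 24.2 CPM in the others, was not among the 10. For each set 1 uncalled gene with a mean of at least 20 CPM was also higher in all its libraries than in every other. RNA added to the libraries with LYZ would not lower genes, yet 9 genes were lower in every library with LYZ than in every other (as many in 110 of 1080 sets of the same makeup). Among them were FN1 (2.24 CPM against 27.6 ± 14.7 and 24.2 ± 10.4, without TMM factors), SPP1 (0.0251 against 9.22 ± 10.5 and 10.2 ± 5.31) and CDH13 (0 against 2.04 ± 1.52 and 1.66 ± 1.22), which varied widely among the other libraries too. RNA added to the other libraries could leave the same pattern, so these genes do not decide against an admixture. These lower genes stay open, as does a difference in state between cultures of PANC-1, which was not tested.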

How the results depend on the processing

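Chosen only after the data were seen were the mitochondrial rRNA scaling, the GC correction, the library sets as terms, the fits without vehicle replicate 2 at 6 h of comparisons that do not use it, and the single-exon difference under all alternatives. Named genes that were called kept direction and call in 10373 of 11119 cases, lost the call in 733 and changed direction in 13, over all alternatives but the mitochondrial rRNA scaling and the stricter thresholds, which were not run on single genes. Uncalled genes stayed so in 2015 of 2193 cases. Named genes were chosen by large changes or small p in the main fit, which favours kept calls. Over all called genes at 0.5 µM and 2 h, DESeq2's size factors kept 965 of 966 calls, but the library sets as terms kept 237. The library-name replicate block kept 811 of 2070 at 5 µM and 2 h, and housekeeping scaling kept 4116 of 6455 at 0.5 µM and 6 h. Over all genes tested, the mitochondrial rRNA scaling kept 208 of 966, 1312 of 2070, 2315 of 6455 and 3654 of 6750 calls in the 4 comparisons with vehicle, with 0 called in the opposite direction. List tests were rerun only with DESeq2's size factors, library totals, the title replicate block, each library left out, the estimated correlation and fry. Called lists kept the call in 444 of 495 cases, but in 8 of 45 with the estimated correlation, and uncalled lists stayed so in 983 of 1045. The cause was not tested for any change given here, except that stricter thresholds call fewer genes by construction and that a scaling moves all genes together. Terms for the library sets also cost power by design in the comparisons of 0.5 µM at 2 h, where the sets coincide with vehicle and 0.5 µM. How many of the lost calls this accounts for was not tested. Fits of only the groups compared have fewer libraries, yet at 2 h they called more genes against vehicle. So did the fits without vehicle replicate 2 at 6 h. In the simulated data 40.3% of 1.5-fold changes were recovered, and 53.7% by DESeq2, so small changes can stay uncalled. That simulation changed 200 genes, far fewer than were called in the real comparisons with vehicle, so its rates do not carry over to them.

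Counts are given as up and down. Scaling to the mitochondrial rRNAs, which rests on 2 genes, gave 103 and 117 at 0.5 µM and 2 h, 51 and 4602 at 5 µM and 2 h, 800 and 1535 at 0.5 µM and 6 h, and 231 up at 5 µM and 6 h. It gave 29 and 5136 between the doses at 2 h, 13 up between them at 6 h, 44 and 177 and then 47 and 72 in the 0.5 µM and 5 µM interactions, and 1 and 2 for vehicle at 6 h against 2 h. Scaling to housekeeping genes gave 255 up at 5 µM and 2 h, 758 and 6133 at 0.5 µM and 6 h, 685 and 6154 at 5 µM and 6 h, and 247 and 3373 and then 356 and 4486 in the interactions. Library totals gave 446 up at 5 µM and 2 h, 1676 and 1759 up at 6 h, and 431 and 851 up in the interactions. TPM with a pseudocount of 1 gave 283 up at 5 µM and 2 h, 1095 and 5067 at 0.5 µM and 6 h, 982 up at 5 µM and 6 h, and 309 and 2704 and then 454 and 3467 in the interactions. With 0.1 these were 278, 1086 and 5057, 982, 300 and 2729, and 448 and 3496.

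Fits of only the groups compared gave 634, 2054, 1545 and 1711 up in the 4 comparisons with vehicle, 17 and 37 between the doses at 2 h, 1305 and 1869 at 6 h, and 514 and 908 up in the interactions. The GC correction gave 843 and 1177 at 0.5 µM and 2 h, 1385 up at 5 µM and 2 h, 20 and 107 between the doses at 2 h, 1376 and 1682 at 6 h, and 2357 up in the 0.5 µM interaction. With the library sets as terms there were 78 and 168 at 0.5 µM and 2 h, 0 and 0 between the doses at 2 h and 313 up at 6 h. At an adjusted p under 0.01 there were 130 and 429 at 0.5 µM and 2 h, 199 and 682 at 5 µM, 1 and 3 and then 225 and 690 between the doses, and 364 and 895 and then 558 and 1173 in the interactions. At least 2-fold changes numbered 78 and 98, 70 and 200, 321 and 1075, and 276 and 1126 against vehicle, 0 and 1 and then 30 and 76 between the doses, and 101 and 425 and then 114 and 437 in the interactions. Between the doses at 2 h, every gene with at least 1 count gave 4 and 25 and DESeq2 gave 10 and 49.

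A replicate block from the number in the library name gave 165 and 657 at 5 µM and 2 h, 0 and 0 between the doses at 2 h, 258 and 700 at 6 h and 514 up in the 0.5 µM interaction. A replicate block from the title number gave 215 and 668, 646 and 1148, 3015 and 3280, and 3116 and 3479 against vehicle. The labels do not say that these numbers pair libraries: across groups, 45 pairs with the same title number had a median r of 0.0083 between residuals and 26 pairs with the same library-name number 0.0035.

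Lists called with an estimated correlation numbered 2 in each of the 4 comparisons with vehicle, and with fry 14, 13, 29 and 28. Over genes of at least 5 CPM the correlations of effects were 0.7985 between the doses at 2 h and 0.8844 at 6 h, against 0.537 and 0.509 in simulated groups without any effect, and 0.6505 and 0.5933 between the times at 0.5 µM and 5 µM, against 0.00368 and 0.0325. With shares of TPM, the 10 most abundant genes differed by 0.89 points at 0.5 µM and 6 h, histones by -0.0109, -0.00488, 0.000455 and 0.00106 points in the 4 comparisons, and ribosomal proteins by 2.97 and 3.17 points at 6 h.

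Directions changed for small rises at 6 h. With housekeeping scaling, PGK1 was at -0.042, COL5A1 at -0.014 and MMP2 at -0.10 at 0.5 µM, and SREBF2 at -0.020, ATP5B at -0.042, PGK1 at -0.0046 and MMP2 at -0.093 at 5 µM. With TPM and pseudocounts of 1 and 0.1, MMP2 was at -0.040 and -0.041 at 0.5 µM and at -0.041 and -0.042 at 5 µM, and ATP5B at -0.00025 and -0.00025 at 5 µM.

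Without each library of the groups compared in turn, and also without vehicle replicate 2 at 6 h in the comparisons that do not use it, counts up and down ranged over 152 to 588 and 432 to 1118 at 0.5 µM and 2 h, 247 to 1919 and 788 to 2109 at 5 µM and 2 h, 2549 to 3243 and 2925 to 3439 at 0.5 µM and 6 h, and 2589 to 3392 and 3176 to 3558 at 5 µM and 6 h. They ranged over 0 to 26 and 3 to 98 between the doses at 2 h, 299 to 954 and 812 to 1475 at 6 h, 652 to 1728 and 1221 to 1901 and then 966 to 2263 and 1581 to 2624 in the interactions, and 0 to 1 and 0 to 0 for vehicle. Lists called ranged over 8 to 12, 7 to 8, 17 to 18 and 11 to 13, and the single-exon difference over -0.56 to -0.43, -0.53 to -0.47, -1.31 to -1.15 and -0.92 to -0.78. The highest counts at 2 h and between the doses came without vehicle replicate 2 at 6 h. At 2 h and 0.5 µM the lowest came without vehicle replicate 2 at 2 h (up) and without 0.5 µM replicate 1 (down), and at 5 µM without 5 µM replicate 3. Where a group kept 2 libraries, the fit took its spread from all groups. Scaling to the 13 mitochondrially encoded mRNAs was not run, as 0 of them were in the table, and vehicle groups of 3 were not split.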

Other observations

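All of the comparisons in this part beyond the fixed lists were chosen after the data were seen.

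Several fixed lists without a call held genes that moved apart. Their counts at 6 h are to be read against those over all 13890 genes tested. There 3097 rose and 3358 fell at 0.5 µM, and 3201 and 3549 at 5 µM. At 0.5 µM the 7 and 8 of 32 interferon genes and the 6 and 7 of 25 NRF2 targets given below are near that share. Of 25 p53 targets, 4 rose and 4 fell in each comparison at 2 h, 6 rose and 9 fell at 0.5 µM and 6 h, and 2 rose and 10 fell at 5 µM and 6 h, where the list median was -0.24 (camera adjusted p = 0.055). At that dose and time TP53INP1, a p53-induced stress gene, fell (-2.58 ± 0.21), as did PHLDA1 (-1.58 ± 0.08), a target of MAPK signalling. MAPK target genes held 5 rises and 12 falls there (adjusted p = 0.132), and at 0.5 µM 6 rises and 10 falls. Interferon-stimulated genes held 7 rises and 8 falls at 0.5 µM and 6 h, and 3 rises and 12 falls at 5 µM. Apoptosis genes, with 5 rises and 8 falls at 0.5 µM and 3 and 7 at 5 µM after 6 h, also went both ways.

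Metabolic and stress lists did so as well. Of 26 hypoxia genes, 11 rose and 4 fell at 0.5 µM and 6 h and 10 rose and 5 fell at 5 µM, with ADM, which encodes the vasodilator adrenomedullin, at 1.33 ± 0.08 and 1.16 ± 0.08. NRF2 targets, the oxidative stress genes, held 6 rises and 7 falls at 0.5 µM and 8 and 8 at 5 µM after 6 h, with SRXN1 at -1.10 ± 0.07 at 0.5 µM and MAFG at -1.27 ± 0.07 and -1.17 ± 0.07. Ferroptosis genes held 8 rises and 3 falls at 0.5 µM and 8 and 2 at 5 µM after 6 h. The unfolded protein response factor XBP1 fell at 5 µM and 6 h (-1.18 ± 0.07), where that list had 11 rises and 3 falls. Epithelial genes held 8 rises and 2 falls and then 9 and 2 in the 2 doses at 6 h. LINC00657, a long noncoding RNA known as NORAD that has 1 exon, fell at 6 h (-1.58 ± 0.09 and -1.20 ± 0.08).

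The library sets differed in other genes as well. Of 16428 genes with at least 20 counts in sum, 18 were higher in every library of the COL1A2 set than in every other library and 0 were lower, and for the LYZ set 25 were higher and 9 lower. As many genes separated 35 of 4860 sets of the same makeup as the COL1A2 set (highest 210, median 0) and 29 of 1080 for the LYZ set (highest 519, median 1). In CPM without TMM factors, LOX stood at 13.4 CPM in the COL1A2 set and at 2.47 and 2.46 CPM in the other libraries, and SPP1 at 0.0251 CPM in the LYZ set and at 9.22 ± 10.5 and 10.2 ± 5.31 CPM (SD) in the others. Within the COL1A2 set SPP1 ran from 0.654 to 22.9 CPM.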
